A study of Drosophila melanogaster with 2 samples.

How the data were processed

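The data are ChIP-seq peak lists from whole embryos of transgenic Drosophila melanogaster expressing Xrp1-eGFP, in 2 biological replicates of 1 group, per the labels. The embryos' age of 8 to 24 hours follows the samples' descriptions. The age label holds a number of hours that does not match it and was not used. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody to GFP, per the labels. The authors aligned reads to dm6 and called peaks with a control, per the deposited notes on how the files derive from each other. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists come from the irreproducible discovery rate (IDR) procedure, which keeps peaks whose ranks hold across replicates or pseudoreplicates. They comprise a conservative list and a second thresholded list of both replicates, a thresholded list of each replicate, and 4 ranked lists to which no threshold was applied. Column meanings follow the narrowPeak and IDR formats and were checked against the values. The deposited signal column is the authors' own peak signal, whose scaling to depth is not stated. The deposited score column is the authors' IDR score, a whole number that follows -log10 of the global IDR, and the thresholded lists hold no peak with a global IDR above 0.01, while 150 ranked peaks at or below that value are missing from the conservative list. Ranked peaks that pass no threshold are those with a global IDR above 0.05. Signal and score rank peaks only within a list, and signals of different lists are not comparable, except that each conservative peak has the same signal in the ranked list of the replicate comparison. The files hold peaks and no reads or counts, so the depth of each replicate is unknown. Intervals cover counting error only and say nothing of the variation between embryos.

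Genes, TSSs and annotation classes came from the Ensembl release 115 annotation, with 18164 genes and 23581 distinct TSS positions, and sequence from the dm6 reference. Positional tests used the summits of the 7534 conservative peaks on arms 2L, 2R, 3L, 3R, 4 and X. A promoter summit lay within 500 bp of a TSS. Classes were assigned in the order promoter, 5' UTR, 3' UTR, coding sequence, other exon, intron and intergenic. Random expectation came from 1000 sets of random positions matched on chromosome, with two-sided permutation tests. Arms were tested by chi-square and exact binomial tests. The 15 motif consensus sequences were searched on both strands in 101 bp windows, against 1 flank window 500 bp to a randomly drawn side, by exact McNemar test, and all 6-base words were tested likewise. Comparisons with GC-matched random windows and with peaks that pass no threshold used Fisher's exact test. Of 29 gene lists, 28 were tested by two-sided Fisher's exact test against all other genes, and the microRNA precursor list matched 0 annotated genes. Strength was compared between the strongest 1883 and the weakest 1883 peaks by the deposited signal, 25% of the list each. Replicate overlap counted peaks sharing at least 1 bp, against 1000 random placements. Benjamini-Hochberg adjustment was made over the motifs, lists, words, classes or arms of each test, and calls used an adjusted p under 0.05.

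The genes and peaks named were Xrp1, Irbp18, crc and w, the 20 strongest conservative peaks with their nearest TSS, up to 4 members per gene list with the strongest summit within 500 bp of a TSS, the 5 strongest peaks of each replicate's list that the other's list lacked, and the 5 most enriched words. These rules, the motifs, the gene lists, the tests and most alternatives were fixed before the data were examined. Words named from the GC-matched comparison, and peaks named among those missing from the conservative list, fall outside the rules and were chosen after their values were seen.

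Alternatives changed 1 choice at a time, such as the peak list, the IDR threshold, each replicate's own list in place of both, the distance to a TSS, the window, the control windows, the background genes and the overlap rule. The lists cut at a global IDR also bring back peaks missing from the conservative list, so that those cut at 0.05 and 0.005 change 2 choices at once. Added after the data were seen were the GC content of summits, the motif comparison between promoter and other peaks, GC-matched controls for words, 10000 random gene lists matched on TSS number, merged regions and a global IDR of at most 0.05. No paired analysis was possible because there is 1 group. The peaks outside the 6 arms (3 conservative and 830 ranked) were left out of the positional tests, and the p column was not used because it holds -1 throughout.

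Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The procedures were tested on simulated data. With nothing planted, 0 of 15 motifs were called, and 1 of 20 unrelated overlap pairs and 1 of 20 random promoter sets had p under 0.05. The planted motif, gene list and word were each called. Beside the planted list, 3 of 27 others were called by Fisher's exact test and 0 of 27 by the matched test.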

Results

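Binding of Xrp1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected 8 to 24 hours after egg laying. Xrp1 is a basic leucine zipper (bZIP) factor with an AT-hook that acts in DNA damage, nutrient stress and cell competition. The flies carried an insertion that expresses Xrp1 fused to enhanced green fluorescent protein (eGFP), and an antibody to GFP was used. The data address where in the embryo's genome Xrp1 is bound. There was 1 group of 2 biological replicates, each with 1 technical replicate. Only peak lists were analysed here, so the read depth of each replicate is unknown. No other genotype, stage or mock precipitation was analysed here, so no comparison between groups was possible, and the comparisons below are between peaks, genomic positions, gene groups and the replicates. All coordinates are in dm6, and the signal of a peak is the authors' own value, used only to describe and rank peaks within a list.

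Xrp1-eGFP had 7537 peaks in the conservative list, the peaks that the authors kept from the comparison of both replicates. On the 6 chromosome arms 729 of them overlapped another conservative peak, and merging overlaps over the whole list gave 7169 regions. The comparisons by peak strength below used unmerged peaks. The strongest conservative peak lay on X at 2703701 to 2704073, in intergenic sequence 38 bp upstream of Ugalt, which encodes a UDP-galactose transporter, with a signal of 3073. Replicate 1's own list gave that peak a signal of 1938 and replicate 2's own list 1143, each list having its own scale. The next peaks were an intronic peak of CG11050 on 2L (6612472 to 6612907, signal 2953), a peak 97 bp upstream of CG14100 on 3L (19590426 to 19590813, signal 2920) and an intronic peak 203 bp upstream of a transcription start site (TSS) of px on 2R (22514118 to 22514483, signal 2838). The Polycomb group gene ph-p followed, with an intronic peak on X (2137174 to 2137556) whose signal was 2505. Of the 20 strongest peaks, 17 had a summit within 500 bp of an annotated TSS, and in 15 of these 17 the summit was upstream of it. They included the promoters of Tcs5 (signal 2294), Art3 and mRpS10 (1 peak, 2278), mRpL41 (2274), Chro (2256), CG18549 (2172), CG5611 (2139), CG1888 (2121), Fkbp14 (2070), PNPase (2060), CenG1A and mRpS23 (1 peak, 2059), CG7601 (2003), RluA-1 (1906) and the casein kinase gene gish (1840). The exceptions were the intronic peaks of CG11050 and CG32772 (signal 1833) and an intergenic peak 11914 bp from the nearest TSS, that of CG13323 (1990). The authors' second list of both replicates held 8735 peaks, 6849 of them identical to a conservative peak, and the replicates' own lists held 7520 and 4402.

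Promoters held far more of the conservative peaks than their share of the genome. A summit lay within 500 bp of a TSS in 2977 of the 7534 conservative peaks on the 6 chromosome arms, or 39.5% (95% Wilson interval 38.4 to 40.6), against a mean of 13.6% (SD 0.397) over 1000 sets of random positions on the same arms. That is 2.91 times the random share, and none of the random sets exceeded 14.9% (two-sided permutation p = 0.001, the smallest that 1000 sets can give). Among ranked peaks that pass no threshold, 17.8% lay this close to a TSS. Within that distance the summits sat on the upstream side of the TSS in 2247 of 2977 peaks (75.5%, interval 73.9 to 77.0; exact binomial p = 4.98e-178), with a median position of -102 bp. The strongest 1883 peaks by signal were at promoters in 45.1% of cases (interval 42.9 to 47.3) and the weakest 1883 in 40.9% (38.7 to 43.1), a difference that passed Fisher's exact test (p = 0.0102). The share did not fall steadily with strength, since it was lowest among the 3768 peaks in between, of which 1358 were at promoters (interval 34.5 to 37.6%). Upstream placement was seen in 83.4% of the promoter peaks among the strongest 1883 and in 60.5% among the weakest 1883.

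**Figure D1:**
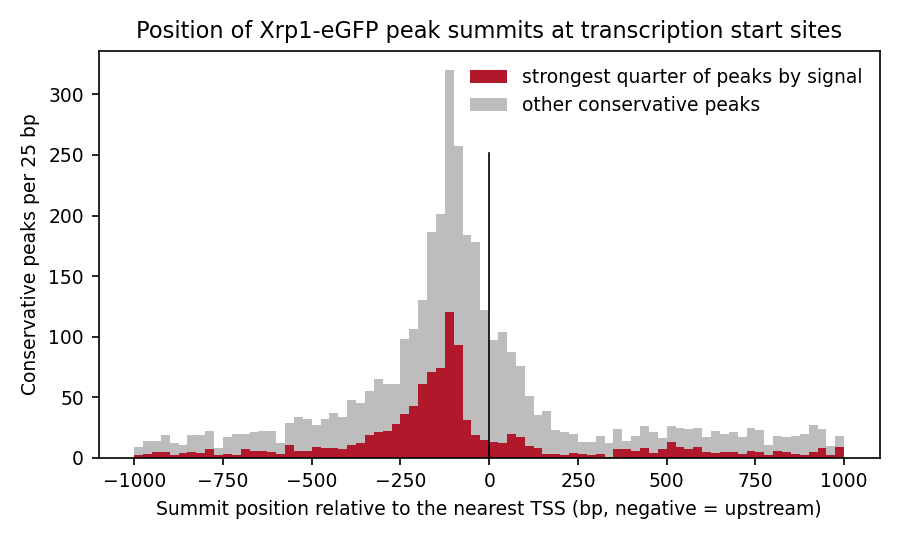
Number of conservative peak summits per 25 bp (y axis) by their position relative to the nearest TSS (x axis, bp, negative values upstream), as stacked bars for the strongest 25% of peaks by the authors' signal and the others. The bars peak upstream of the TSS, where the median of summits within 500 bp is -102 bp.

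Coding sequence was nearly free of Xrp1-eGFP summits, and 3' untranslated regions (UTRs) held fewer than random positions gave. Only 28 summits (0.372%, interval 0.257 to 0.537) lay in coding sequence outside promoters, against 13.1% of random positions, and 82 (1.09%) lay in 3' UTRs against 5.05%. Both shares differed from the random sets (permutation, adjusted p = 0.00175 over 7 classes). Intergenic sequence beyond promoters held 17.8% of summits against 27.3% at random (permutation, adjusted p = 0.00175). Introns held 2994 summits, 39.7% against 39.4%, with no difference detected (permutation, adjusted p = 0.536). Class shares add up to the whole, so the excess at promoters lowers what is left for the other classes. The intron and intergenic comparisons therefore do not show placement among non-promoter summits alone. The 5' UTRs away from other promoter sequence held 0.531% against 0.782% (permutation, adjusted p = 0.0182), a difference that was not called in either replicate's own list (adjusted p = 0.133 and 0.173) or in the second list of both replicates (0.0909; range over the alternatives 0.001 to 0.173). Other exons held 0.942% against 0.817%, with no difference detected (permutation, adjusted p = 0.295), but were called higher in the second list of both replicates and in the lists of replicates 1 and 2 (adjusted p = 0.0056, 0.0238 and 0.014). When promoters were not set apart as a class, intergenic sequence held 37.0% of summits and lay above the random share of 30.6%, as did introns (49.7% against 42.6%), other exons (2.77% against 1.77%) and 5' UTRs (7.79% against 3.38%; permutation, adjusted p = 0.001 for each).

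Chromosome 4, the small arm rich in heterochromatin, carried the fewest peaks for its length. It had 35 conservative peaks, 26.0 per Mb (exact Poisson interval 18.1 to 36.1), which is 0.461 times the number expected from length (exact binomial, adjusted p = 1.44e-06). Arms 2L and 3L had 61.4 and 60.7 peaks per Mb, 1.09 and 1.08 times the expected numbers, and 2R and 3R had 51.6 and 53.3, 0.916 and 0.947 times (adjusted p between 0.000752 and 0.0110). These counts leave out 148 peaks with a global IDR of at most 0.01 that the conservative list lacks, 93 on 3R and 39 on 2L. No alternative brought them back for the arms, so the shortfall on 3R may rest on their absence. The X chromosome, with 56.7 peaks per Mb, showed no detectable departure from its expected number (exact adjusted p = 0.739), but was called higher in replicate 1's own list (1.05 times, adjusted p = 0.0409; range over the alternatives 0.0409 to 0.919). Counted per annotated gene, with promoter peaks only, none of the 6 arms passed the test, by adjusted p or by an unadjusted p under 0.05 (exact binomial; chi-square p = 0.726), and chromosome 4 was at 0.827 times the expected number.

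The gene of the factor itself held a cluster of peaks. Within 3000 bp of Xrp1 (3R, 18914968 to 18926989) there were 9 conservative peaks, the strongest at 18918105 to 18918359, in intronic sequence 28 bp upstream of an internal TSS, with a signal of 590 and rank 312 (330 in replicate 1's list and 251 in replicate 2's). The second was intergenic, 820 bp upstream (signal 168), and the other 7 had signals of 59.5 to 136. Ranked peaks within 10000 bp of the gene that pass no threshold were strong as well, with a median signal of 27.2, at percentile 98.6 of same-sized regions around other genes. Irbp18, the gene of the bZIP partner of Xrp1, had a peak 166 bp upstream of its TSS on 3L (11098227 to 11098473, a position also annotated as 3' UTR; signal 420, rank 623). The TSS nearest to that summit was that of another gene. Near crc, which encodes the fly ATF4, a peak with a signal of 99.1 lay 581 bp upstream of the TSS on 2L (21310103 to 21310466) and overlapped a weaker one (signal 28.5) at 381 bp. Both rested on the same pair of replicate peaks, so the count of crc among occupied genes depends on the weaker one. At w, the eye colour gene often carried by transgenes, no conservative peak lay within 3000 bp of the gene, and the strongest ranked peak there had a signal of 47.4 and did not pass the threshold.

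Aminoacyl-tRNA synthetase, ribosomal protein, integrated stress response, bZIP factor, DNA repair and autophagy genes had Xrp1-eGFP at their promoters more often than other genes. Over the whole annotation 3640 of 18164 genes had a conservative summit within 500 bp of a TSS. Of 28 gene lists tested, 10 lay above and 4 below the other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the lists). The other genes include noncoding ones, and genes differ in their number of TSSs. Against random lists matched on TSS number, a test added after the data were seen, the lists named above were still called. Their matched shares ran from 25.4% (autophagy) to 30.6% (synthetases). The bZIP list had the highest adjusted p among them (permutation, adjusted p = 0.0252). The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were occupied in 13 of 20 genes (65.0%, interval 43.3 to 81.9; Fisher's adjusted p = 7.15e-05), with the strongest summits at GluProRS (signal 585, 139 bp upstream), IleRS (523), SerRS (494) and ThrRS (239). Cytosolic ribosomal protein genes were occupied in 41 of 89 (46.1%, interval 36.1 to 56.4; Fisher's adjusted p = 1.59e-07), led by RpL34b (575), RpL32 (453), RpS20 (392) and RpL14 (245). Mitochondrial ribosomal protein genes were occupied in 30 of 73 (41.1%, interval 30.5 to 52.6; Fisher's adjusted p = 0.000159), among them mRpS10, mRpL41, mRpS23 and mRpL23 (1553) from the strongest peaks of the list. A summit counted for every gene with a TSS within 500 bp. The peaks of mRpS10 and mRpS23 lay nearer to Art3 (120 bp) and CenG1A (102 bp). For the peaks named here and below at GluProRS, RpL34b, RpL32, mei-41, Atg2 and Atg7, the nearest TSS was likewise that of another gene. So it was for those at His2Av, elav, PPO3 and Cyt-c-d. Other named peaks of these and the following lists were also shared, such as IleRS with Hem, RpL14 with Nelf-E and Irbp with mgr.

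Stress and integrated stress response genes were occupied in 13 of 24 (54.2%, interval 35.1 to 72.1; Fisher's adjusted p = 0.000613). The strongest were aay, the phosphoserine phosphatase of serine synthesis (3L, 9422889 to 9423216, signal 1137), Sesn, which encodes sestrin (916), Ldh, which encodes lactate dehydrogenase (693), and Xbp1, a factor of the unfolded protein response (449). The bZIP factor genes were occupied in 12 of 24 (interval 31.4 to 68.6; Fisher's adjusted p = 0.00252), led by REPTOR (784), Atf3 (725), Xrp1 and Xbp1. DNA damage and repair genes were occupied in 18 of 35 (51.4%, interval 35.6 to 67.0; Fisher's adjusted p = 0.000138), with Irbp, the fly Ku70 gene (683), mei-41, the ATR kinase gene (584), and RnrS, the small subunit of ribonucleotide reductase (398), beside Xrp1. Autophagy genes were occupied in 14 of 25 (56.0%, interval 37.1 to 73.3; Fisher's adjusted p = 0.000240), among them Atg2 (411), Atg7 (371) and Atg9 (311). Several genes, such as Xrp1, REPTOR, Xbp1 and Sesn, belong to more than 1 of these lists, so the lists are not independent of each other.

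Cell cycle and replication genes were occupied in 14 of 33 (42.4%, Fisher's adjusted p = 0.00798), with Dp (430), dpa (223), BubR1 (204) and Mcm2 (172) the strongest, but the call was lost in replicate 2's own list (adjusted p = 0.0598; range over the alternatives 0.000647 to 0.158). Small nuclear RNA genes were occupied in 13 of 32 (40.6%, Fisher's adjusted p = 0.0148), led by snRNA:U1:95Ca (273), and that call was lost in replicate 1's own list (adjusted p = 0.192; range over the alternatives 0.00168 to 0.192). The calls of the other 8 higher lists and of the 4 lower lists were made in both replicates' own lists as well. The number of lists called changed with other settings. With genes that have a ranked peak of any strength as background, 8 lay above and 3 below, and at a global IDR of at most 0.05, 9 and 3. With protein-coding genes alone as background, 23 lists were tested, of which 8 lay above and 1 below. Within 1000 bp of a TSS 12 lay above and 2 below, and within 2000 bp 14 and 2. Protein-coding genes as a class were occupied in 23.2% and other genes in 9.62% (Fisher's adjusted p = 5.91e-92). Below the other genes were long noncoding RNA genes (326 of 3261, Fisher's adjusted p = 1.59e-62), small nucleolar RNA genes (5.95%, adjusted p = 8.03e-10), transfer RNA genes (14.1%, adjusted p = 0.0234) and histone genes, of which 2 of 115 were occupied (1.74%, adjusted p = 3.92e-08). The 2 occupied histone genes were His2Av (signal 224) and His3.3B (136), which lie outside the repeated histone cluster. A further peak with a global IDR of at most 0.01 lay 72 bp upstream of His3:CG31613 (2L, 21424939 to 21425302, signal 103). It is among the peaks missing from the conservative list. Only 7 of the 115 had a ranked peak of any strength at a TSS, and among genes with such a peak the list no longer passed the test (Fisher's adjusted p = 1; range over the alternatives 3.61e-14 to 1). Within 2000 bp of a TSS, transfer RNA and small nucleolar RNA genes lay above the other genes, by 6.47 and 12.1 percentage points (Fisher's adjusted p = 0.0380 and 0.000214).

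No difference from other genes was detected within 500 bp of a TSS for the tissue, signalling and remaining stress groups. Among them, glial genes were called higher within 1000 bp (Fisher's adjusted p = 0.0281; range over the alternatives 0.0281 to 0.581) and glutathione and antioxidant genes within 2000 bp (0.0374; range 0.0374 to 0.840). The 7 of 21 apoptosis genes occupied (33.3%, interval 17.2 to 54.6; Fisher's adjusted p = 0.259) included hid (signal 366), Traf4 (143), Drice (111) and Diap1 (108). Glutathione and antioxidant genes were occupied in 18 of 63 (28.6%, Fisher's adjusted p = 0.186), with a strong peak at GstE13 (1363). Oxidative phosphorylation genes were occupied in 25 of 84 (29.8%, Fisher's adjusted p = 0.0729; called within 250, 1000 and 2000 bp, with a range over the alternatives of 0.0185 to 0.642), led by Cyt-c-d (870). Proteasome genes (10 of 48, Rpn3 at 426), heat shock and chaperone genes (8 of 29, Hsp27 at 1072 and Hsp26 at 381) and genes of JNK, wound and cell competition signalling (6 of 28, Stat92E at 258) had adjusted p of 0.923, 0.490 and 0.923. Of the tissue markers, 5 of 12 glial genes (moody at 820; Fisher's adjusted p = 0.128), 6 of 26 muscle genes (tin at 1006; 0.767), 4 of 21 tracheal and epidermal genes (trh at 320; 1), 3 of 22 hemocyte and fat body genes (PPO3 at 296; 0.762), 2 of 17 midgut and endoderm genes (fkh at 307; 0.735), 3 of 14 germline genes (bgcn at 114; 1) and 6 of 35 Hox and segmentation genes (bcd at 276; 0.923) were occupied. Neuronal markers were occupied in 2 of 24 genes, elav (1194) and Shab (71.5), or 8.33% (interval 2.32 to 25.8; Fisher's adjusted p = 0.300). Against random lists matched on the number of TSSs, a test added after the data were seen, the neuronal list lay below its matched share of 34.0% (permutation, adjusted p = 0.00933; range over the alternatives 0.00933 to 0.712), while the transfer RNA list no longer passed the test (adjusted p = 0.113).

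**Figure D2:**
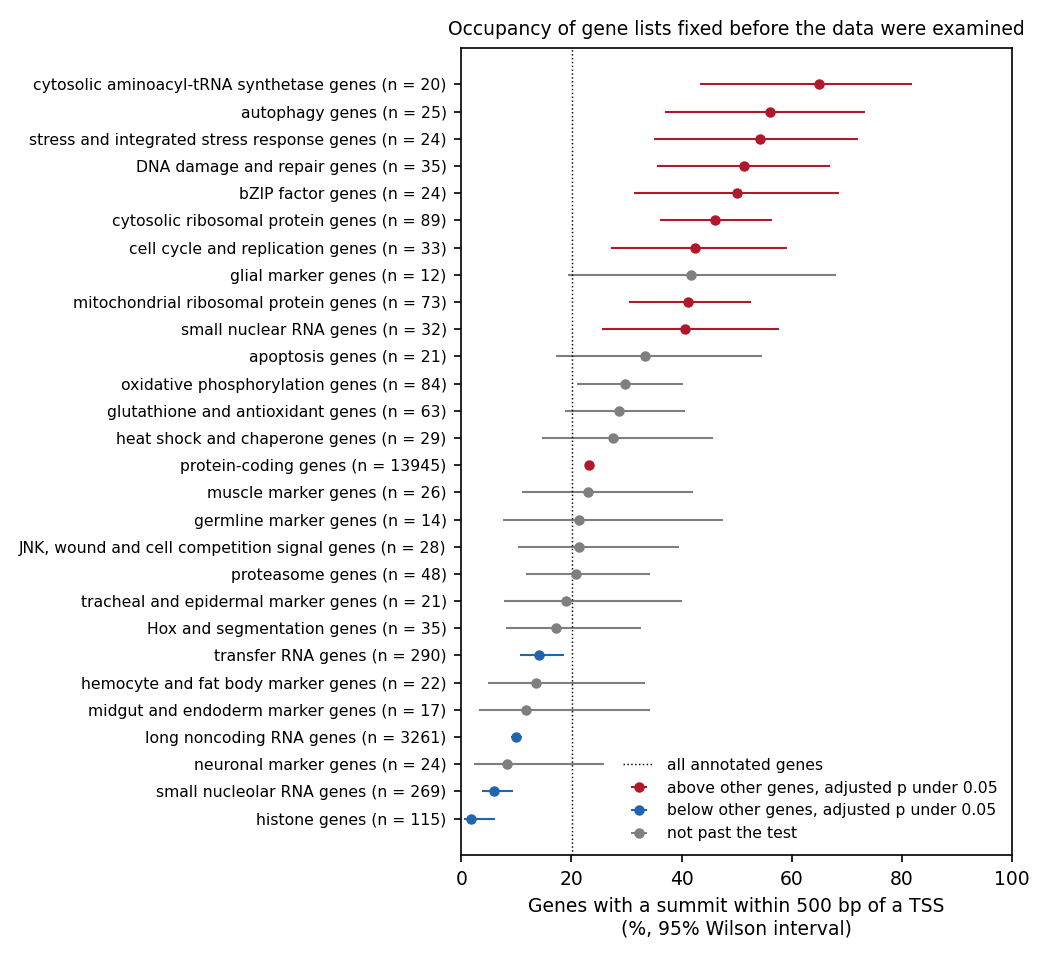
Share of each list's annotated genes with a conservative summit within 500 bp of a TSS (x axis, %; points with 95% Wilson intervals), with the list's number of genes in brackets and the share over all 18164 genes as a dotted line. Aminoacyl-tRNA synthetase genes stand highest at 65.0% and histone genes lowest at 1.74%.

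The binding sites of the C/EBP and ATF families, to which the bZIP domain of Xrp1 is related, were not more frequent at Xrp1-eGFP summits than in DNA of the same base composition. Within 50 bp of the summit, the C/EBP-ATF composite was present at 20 of 7534 conservative peaks (0.265%, interval 0.172 to 0.410) and in 22 windows (0.292%) drawn 500 bp to 1 side of the same summits (exact McNemar test, adjusted p = 1 over 15 motifs). The relaxed C/EBP consensus was present at 5.39% of summits (interval 4.90 to 5.92) and in 4.29% of flanks (adjusted p = 0.00433), but in 6.25% of random windows matched on GC content (Fisher's exact test, adjusted p = 0.0971). The call against flanks was lost in each replicate's own list (exact adjusted p = 0.603 for replicate 2 alone and 0.152 for replicate 1 alone; range over the alternatives 3.67e-05 to 0.603) and beyond 500 bp of a TSS (0.538). Any of the 4 C/EBP consensus forms was present at 6.68% of summits, in 5.52% of flanks and in 7.57% of GC-matched windows. Among the strongest 1883 peaks by signal the share was 7.38% (interval 6.29 to 8.65) and among the weakest 1883 it was 5.95% (4.97 to 7.11), with Fisher's exact p = 0.0892. That difference was 2.71 percentage points in replicate 1's own list (exact p = 0.000963) and 0.909 in replicate 2's (p = 0.416), and 2.79 between the strongest and weakest 753 conservative peaks (Fisher's exact p = 0.0335). The strongest 1883 conservative peaks also had a lower summit GC content than the weakest 1883 (29.5% against 38.7%). No GC-matched control was made for the difference by strength, so it cannot be told apart from base composition. The composite was present in 5 of the strongest and 3 of the weakest 1883 peaks (exact p = 0.726).

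Of the other motifs, DRE and GATA sites were more frequent at summits than in both flanks and DNA of the same base composition. The DRE, the DNA replication-related element and site of Dref and BEAF-32, was present at 91 summits (1.21%, interval 0.985 to 1.48) and in 0.226% of flanks, a ratio of 5.35 (exact adjusted p = 3.11e-12), and in 0.372% of GC-matched windows (adjusted p = 7.62e-08). Of these 91 summits, 81 lay within 500 bp of a TSS, which is 2.72% of promoter peaks against 0.219% of the other peaks (Fisher's exact test, adjusted p = 9.04e-22, a test added after the data were seen). Away from promoters the DRE was no more frequent at summits than in flanks (exact adjusted p = 1; range over the alternatives 7.32e-28 to 1). GATA factor sites were present at 113 of 7534 summits (interval 1.25 to 1.80%) and in 0.876% of flanks (exact adjusted p = 0.00118), and in 0.995% of GC-matched windows (adjusted p = 0.0323). The GATA call was lost in windows of 25 bp on either side (exact adjusted p = 0.727; range over the alternatives 1.01e-07 to 0.727). It was also lost among peaks more than 500 bp from a TSS (exact adjusted p = 0.0609) and among those within it (0.446). The TATA box was present at 1.13% of summits against 0.557% of flanks (exact adjusted p = 0.000638), but not above the GC-matched 1.27% (adjusted p = 0.758). Within 500 bp of a TSS the TATA call was lost (exact adjusted p = 0.224). GAGA sites changed direction with the control, being present at 1.43% of summits, 2.35% of flanks (exact adjusted p = 0.000202) and 0.770% of GC-matched windows (adjusted p = 0.000883). The GAGA call against flanks was lost in windows of 100 bp on either side (exact adjusted p = 0.202) and within 500 bp of a TSS (0.983). Fewer summits than flanks held the antioxidant response element (1.91% against 3.04%, exact adjusted p = 6.35e-05), the E-box (0.690% against 1.17%, 0.00555), the Zelda site (0.279% against 0.703%, 0.000769) and the CRE (0.0929% against 0.279%, 0.0209). The CRE call was lost under all 10 alternatives (exact adjusted p from 0.0609 to 1). The Zelda call was lost in windows of 25 and 100 bp on either side (exact adjusted p = 0.0878 and 0.202) and beyond 500 bp of a TSS (0.141). The antioxidant element's call was lost in replicate 2's own list (exact adjusted p = 0.108) and within 500 bp of a TSS (0.184), and the E-box call within 500 bp of a TSS (0.446). For none of these 4 was a difference from GC-matched windows detected (Fisher's adjusted p between 0.758 and 1). The C/EBP palindrome (0.159% of summits), the TTGCAA core (1.08%), the PAR bZIP site (0.119%), AP-1 (0.810%) and Motif 1 (0.0929%) showed no detectable difference from flanks (exact adjusted p = 1, 1, 1, 0.736 and 0.270). Motif 1, the M1BP site of core promoters, was called higher in windows of 100 bp on either side (25 summits against 4 flanks, exact adjusted p = 0.000389) and against peaks that pass no threshold (0.0342; range over the alternatives 0.000389 to 0.606).

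**Figure D3:**
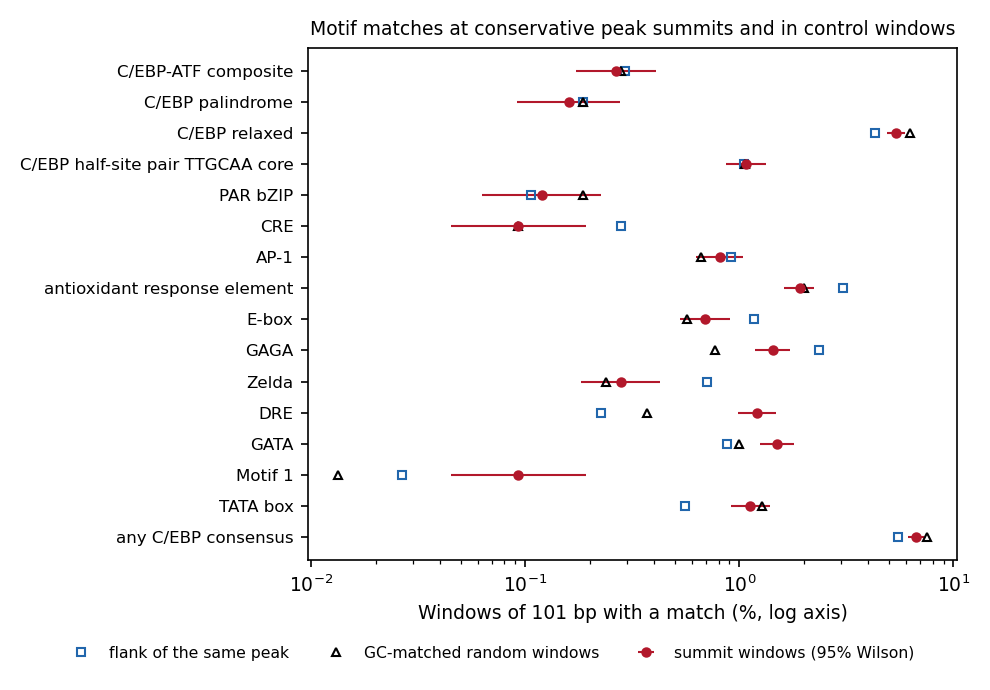
Share of windows reaching 50 bp to either side with a match of each motif (x axis, %, log scale) at conservative summits (filled circles with 95% Wilson intervals), in 1 flank of the same peak (open squares) and in random windows matched on GC content (open triangles). The DRE circle lies at 1.21%, right of its flank at 0.226% and its GC-matched control at 0.372%.

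Xrp1-eGFP summits were rich in A and T. The sequence within 50 bp of conservative summits had a mean GC content of 33.6% ± 9.88 (SD, n = 7534 peaks), against 42.7% ± 10.1 in the flanks and 42.2% over the 6 arms. The mean difference from the flank was -9.08 percentage points (95% interval -9.41 to -8.74), and the summit was lower in 5523 peaks (73.3%). The dip was deeper at stronger peaks, with a summit GC content of 29.5% and a difference of -13.6 (interval -14.2 to -13.0) for the strongest 1883 peaks, and 38.7% and -2.87 (-3.56 to -2.17) for the weakest 1883. Ranked peaks that pass no threshold had 43.7% at the summit, 1.74 percentage points above their flanks. The GC content measure was chosen after the data were seen. Among all 2080 words of 6 bases, 486 were more frequent at summits than in flanks and 1083 less frequent (exact McNemar, adjusted over the words). All 36 words made only of A and T were among those 486, led by AAATAT (2656 summits against 1205 flanks, exact adjusted p = 8.84e-155), TAAATA, TTAAAA, AATATA and AAATAA. Against GC-matched windows, a control also added after the data were seen, 173 words were more frequent, 5 of them made only of A and T, and 153 were less frequent. The words that led that list were ACAGTG (6.34% against 2.87%), ACACTG (6.42% against 3.13%) and CGATAG (3.72% against 1.81%).

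**Figure D4:**
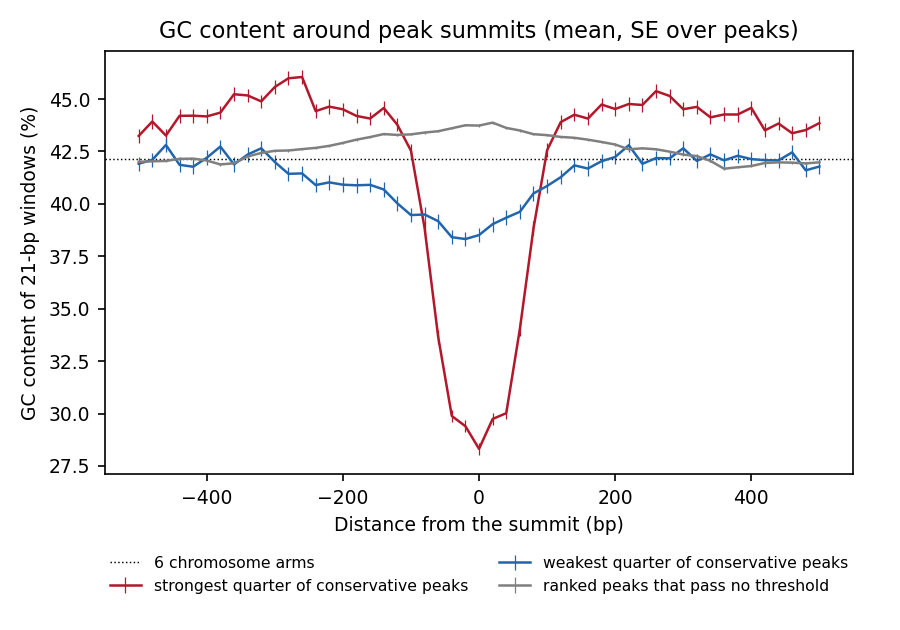
Mean GC content in windows of 21 bp (y axis, %) by distance from the summit (x axis, bp) for the strongest 25% and the weakest 25% of conservative peaks and for ranked peaks that pass no threshold, with bars of 1 SE over peaks and the mean of the 6 arms as a dotted line. At the summit the means are 28.3%, 38.5% and 43.7%.

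The replicates shared most of the peaks of the shorter list. Of replicate 2's 4402 thresholded peaks, 3941 overlapped a thresholded peak of replicate 1 (89.5%, interval 88.6 to 90.4), against a mean of 3.30% over 1000 random placements (two-sided permutation p = 0.001, the smallest that 1000 sets can give). Of replicate 1's 7520 peaks, 3896 overlapped one of replicate 2 (51.8%, interval 50.7 to 52.9; random mean 1.98%). Across the 90143 ranked peaks on the arms, the Spearman correlation between the replicates' signals was 0.431 and Pearson's r of the log2 signals 0.573. Over the conservative peaks alone the Spearman correlation was 0.771 and over the strongest 10000 ranked peaks 0.694. The conservative peaks were kept because their ranks hold across these same replicates, and the strongest 10000 were picked by the signal of both. Neither value is therefore an independent measure of agreement. Peaks are not independent replicates, so no p is given.

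Peaks of 1 replicate alone were weaker and, for replicate 1, lay less often at promoters. The 3624 peaks found only in replicate 1's thresholded list had a median signal of 58.8, against 132 for the 3896 shared ones, and lay within 500 bp of a TSS in 36.6% of cases against 40.8% (Fisher's exact p = 0.000241). The strongest of them were near CG7560 (309), CG15408 (244), bin3 (242), E(spl)m7-HLH, a Notch target (241), and Tab2 (223). In replicate 2's ranked list of any strength, peaks with signals of 103, 98.5 and 25.5 overlapped those at bin3, E(spl)m7-HLH and Tab2, and 3412 of the 3624 (94.2%, interval 93.3 to 94.9) overlapped some ranked peak of replicate 2, against 27.2% at random. The 460 peaks found only in replicate 2's list had a median signal of 46.2 against 72.5 for the shared ones and a promoter share of 39.3% against 40.7% (Fisher's p = 0.616), which differed under a reciprocal overlap of 50% (-3.70 percentage points, p = 0.0223). The strongest lay in introns of JIL-1, which encodes a histone H3 kinase (148), aralar1 (140), PRAS40 (128), Tab2 (128) and ERp60 (127). The peak at ERp60 overlapped a ranked peak of replicate 1 (signal 72.1), and the peak at Tab2 (2R, 19293526 to 19293609) lay just beside the one found only in replicate 1 (19293650 to 19293854). No difference in the share with any C/EBP consensus was detected between unshared and shared peaks in replicate 1 (6.48% against 6.49%, Fisher's p = 1) or replicate 2 (5.43% against 6.45%, p = 0.479). The mean summit GC content, which was not tested here, was 40.5% in unshared and 32.6% in shared peaks of replicate 2. In replicate 1 it was 33.1% and 31.6%.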

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

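The GC content test of the peaks below was chosen before its result was seen, while the choice of these peaks and the other comparisons of them were made after. In the replicate comparison, 150 ranked peaks had a global IDR of at most 0.01 but were missing from the conservative list. The location, motif and gene list comparisons of the report leave these peaks out. Alternative settings bring them back for the promoter share and the gene lists but not for the motifs, the annotation classes or the chromosome arms. The correlation over ranked peaks includes them. The strongest, on 2L at 480896 to 481296 in an intron 1410 bp upstream of a TSS of cbt, had a signal of 3082.8 in the ranked list, where the strongest conservative peak has 3073, and signals of 1938 and 1161 in the replicates' ranked lists. The next were at Lk6 on 3R (signal 2140), at the promoter shared by CG18428 and eIF4EHP (1342) and at larp (1251). Of the 148 on the arms, 93 were on 3R and 39 on 2L. Of these 148, 73 (49.3%, Wilson interval 41.4 to 57.3) lay within 500 bp of a TSS, against 39.5% of conservative peaks (Fisher's exact p = 0.0174). Several of the 148 lay at the same gene, such as Kdm2, tara and spen. Some, such as those at lncRNA:Hsromega, rested on the same pair of replicate peaks. Intervals and tests over the 148 treat them as independent, so they overstate the precision.

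Per the deposited notes, the thresholded lists also derive from a further reference file that is not described, and filtering against a set of excluded regions is a candidate explanation for the missing peaks that was not tested. Signal of another kind than Xrp1 binding is a further explanation. It predicts no dip in GC content, and the left-out peaks had a dip of -3.14 percentage points (95% interval -5.80 to -0.487), between that prediction and the -9.08 of conservative peaks, so on this test the kinds cannot be told apart, because the interval excludes both values and reaches above the limit of -1 set beforehand. The design gives no group against which a biological explanation could be tested.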

How the results depend on the processing

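Settings added after seeing the data are the IDR limit of 0.05, merged regions, matched gene lists and GC-matched words. Of the main results' alternative values, 59 kept their direction and side of the threshold or their size, 8 moved and 3 passed a threshold newly; of the other values, 446 kept theirs, 14 passed newly, 47 no longer passed and 13 reversed. The promoter share stayed between 31.0% and 62.1% over all its settings, above random sets in each. The peak number ranged from 4402 to 7520 in the replicates' own lists. The Spearman correlation of the replicates' signals was 0.771 over conservative peaks and 0.694 over the strongest 10000, against 0.431 over all ranked peaks. Both smaller sets were selected on the same replicates, so their values are not independent checks. Without a promoter class, 5' UTRs (7.79%) and intergenic sequence (37.0%) rose above random and introns (49.7%) and other exons (2.77%) passed newly, since promoter summits then fall into them. With promoters kept, other exons also passed newly in the second list and in each replicate's own. Counted as promoter peaks per gene, 0 arms differed. With GC-matched controls some motif differences, all past the threshold against flanks, changed sign. In percentage points they were relaxed C/EBP -0.863, any C/EBP -0.889, TATA box -0.146, E-box 0.119, GAGA 0.664 and Zelda 0.0398. Of those with an adjusted p, GAGA alone passed against GC-matched windows (Fisher's exact test, adjusted p = 0.000883). Any C/EBP, left out of the adjustment, had an unadjusted Fisher's exact p of 0.0365. GAGA was at 0.0168 against peaks that pass no threshold. Motifs called above flanks numbered 4 in the main test, 1 beyond 500 bp of a TSS (the TATA box) and 2 within it (DRE and relaxed C/EBP). Not called, DRE turned to -0.0219 beyond 500 bp and CRE to 0.0336 within it. The C/EBP difference by strength, made without a GC-matched control, was 2.79 points between the strongest and weakest 753 peaks and 0.909 to 2.71 in the replicates' own lists. Within 2000 bp, transfer RNA (6.47 points) and small nucleolar RNA genes (12.1) lay above other genes. The replicate 2 promoter difference was -3.70 points under reciprocal overlap. Enriched words numbered 1697 at 8 bases, where more words were tested, and 173 against GC-matched windows. Beyond those explained by construction, the cause was not tested. Leaving out a replicate is impossible for overlap and correlation, and ranking by -log10 p was not run, since that column is constant. Unknown depth limits how far the replicates' peak numbers can be compared.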

Other observations

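Chosen after the results were seen were the test of C/EBP sites within 200 bp of the summit and the comparison of Xrp1 with peak-rich regions; the other tests here were chosen before. Among the 20 strongest conservative peaks the summit GC content ran from 19.8% to 39.6%, with any C/EBP consensus at 3 of them and 7 at promoters shared with another gene. Among noncoding RNA genes, strong peaks lay near lncRNA:CR31044 on 3R (signal 1756, 113 bp upstream) and lncRNA:CR44339 on 2R (1547, 151 bp upstream), and near tRNA:Tyr-GTA-1-8 on 3R (882, 208 bp upstream). On the Y chromosome there were 89 ranked peaks and 0 conservative ones.

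Summits were AT-rich without holding more C/EBP sites than DNA of the same composition. Sites lying away from the called summit were argued against, since any C/EBP consensus was present within 200 bp of 21.9% of summits and in 25.2% of GC-matched windows, a difference of -3.27 percentage points (95% interval -4.62 to -1.91). The composition of promoters in general was argued against by the summits more than 2000 bp from a TSS, where the difference in GC content was -9.09 percentage points (-9.58 to -8.60). Not every AT-rich stretch gave a conservative peak. Of 36449 random windows as AT-rich as the median summit or more, 2.47% (2.31 to 2.63) lay within 100 bp of a conservative summit. Among all windows the share was 1.17%. The number of peaks allows at most 6.21%, so the planned limit of 50% could not be reached and that test decided nothing. A tendency of AT-rich stretches to give peaks stays open. Contact through the AT-hook of Xrp1, or open chromatin that is itself AT-rich at its centre, may account for the pattern, and neither was tested.

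The 32021 bp around Xrp1, 10000 bp on either side included, held 11 conservative peaks, against a median of 2 and a 95th percentile of 6 over 2000 regions around other genes. Extra copies of the locus in the tagged strain could raise weak signal over the whole region as well, unless the control used in peak calling carried them too. The ranked peaks there that pass no threshold had a median signal of 27.2, at percentile 98.6 of 1833 regions around other genes. Strong peaks raising the weak ones beside them were argued against, since that median lay at percentile 99.6 of 675 regions with at least 7 conservative peaks. Those regions were chosen by their number of peaks and not by peak strength. Extra copies are a candidate explanation for part of the cluster, but these tests do not single them out. Binding of Xrp1 to its own gene stays open and was not tested.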
